A study of Mus musculus with 20 samples.

How the data were processed

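RNA from mouse spinal cord was hybridised to Affymetrix whole-transcript arrays, 1 array per sample, in 4 groups of 5 arrays. Control mice and Cx30GRko mice, whose glucocorticoid receptor gene is removed by Cre recombinase in cells that express connexin 30, received an intraperitoneal injection of saline or of dexamethasone (Dex, 4 mg/kg), a synthetic agonist of the receptor, and tissue was taken 4 h later. The arrays titled Tg were read as the Cx30GRko arrays and those titled wt as the controls. No pooling of animals was stated. The authors deposited 1 table of probe set values on the log2 scale. The tool named in the submitters' processing notes was oligo. Its version, the normalization method, the genome build and the annotation were not given in the sources used here.

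The deposited log2 values were used as they stood. All 20 arrays had the same mean of 4.64, so the values had been normalised between arrays. For every probe set the mean over the 8 arrays of replicates 4 and 5 equalled the mean over the 12 arrays of replicates 1 to 3, with a largest difference of 4.5e-09, whereas a split of the arrays within replicates 1 to 3 gave a median difference of 0.10. The values had thus been centred within 2 sets of arrays, which the labels do not mention. Each set holds every group in equal numbers, so group differences over all arrays are averages of those within the sets. These sets were treated as batches, and values within each set (replicates 1 to 3, replicates 4 and 5) stand beside the pooled ones.

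The table held 41345 probe sets, of which 23521 had 1 gene symbol, 1814 had several and 16010 had none. For each of the 22180 genes with a symbol the probe set with the highest mean over the 20 arrays was tested, a choice that mattered for the 1082 genes with several probe sets. No filter on dim probe sets was applied. Differences between groups were tested with limma 3.58.1 in R 4.3.3. A mean per group was fitted to all 20 arrays (16 residual degrees of freedom, 5.66 prior degrees of freedom) with moderated variances and no block. The centring within the array sets had used up 1 further degree of freedom, which this fit did not count. A fit with a block for the array set counts it, and its calls stand beside the reported ones. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over all 22180 genes within each of the 6 comparisons, and genes with an adjusted p under 0.05 were called. The comparisons were Dex against saline in control mice, Dex against saline in Cx30GRko mice, the difference between these 2 effects (the interaction), Cx30GRko against control under saline, Cx30GRko against control under Dex, and the mean of the 2 Dex effects. The interaction was also adjusted over the genes called for the mean Dex effect alone. In this balanced design the estimate of that effect is uncorrelated with that of the interaction. Both tests use the same estimate of each gene's spread, so the choice of genes is not fully independent of the interaction test. Attenuation was measured over the same genes as the median of the interaction, signed so that negative values stand for a smaller Dex effect in Cx30GRko mice. It was tested by an exact two-sided permutation of genotype within each treatment (63504 regroupings), which exchanged arrays freely between the 2 array sets.

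Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01, and again with an estimated correlation. P-values were adjusted over the 25 lists within each comparison. The 25 lists held 442 members, of which 402 were measured, and members without a probe set of their own were not analysed here. The lists were glucocorticoid receptor targets, glucocorticoid receptor machinery, circadian clock, immediate early genes, NF-kB and inflammatory genes, glucose, glycogen and lactate, glutamate, potassium and amino acid handling, lipid droplet and fatty acid oxidation, cholesterol synthesis, heat shock and chaperones, reactive astrocyte genes, and markers of astrocytes, microglia, oligodendrocytes, oligodendrocyte precursors, neurons, endothelial cells, mural cells, meningeal fibroblasts, ependymal cells, erythrocytes, neutrophils and blood monocytes, lymphocytes, Schwann cells and peripheral roots, and skeletal muscle.

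The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison the rule names the 10 largest rises and the 10 largest falls among called genes. Where fewer than 5 genes were called it adds the 5 with the smallest p, reported as not significant. It also takes up to 4 members with the smallest p of each list discussed, always Nr3c1, Gjb6, Fkbp5, Tsc22d3, Per1 and Sgk1, and for the interaction among the Dex genes the 10 with the smallest p and 5 with the most similar effects in both genotypes. A gene named outside the rule is marked as chosen after its values were seen.

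Results were recomputed with a block for the replicate number in the titles, dim genes left out, all probe sets tested, quantile normalization again, medians subtracted, cyclic loess, array weights, a trended robust prior, only the groups compared in the fit, an adjusted p under 0.01, a change of at least 1.2-fold, and each array left out in turn. Camera with an estimated correlation, fry (a self-contained rotation test) and a replicate block served for the lists, and the genes called in 1 genotype for the attenuation. The replicate number was not used as a pairing in the reported fit. Across genes, arrays with the same number in 2 groups had a median correlation of deviations from their group means of -0.09. The same-number array was the best match in 1 of 30 cases. Same-number arrays always share an array set, and the centring by itself lowers correlations within a set. The check therefore cannot show whether the arrays were paired. A further 5 fits were added once the array sets had been seen: a block for the array set, replicates 1 to 3 alone, replicates 4 and 5 alone, all arrays but Cx30GRko Dex replicates 4 and 5, and 1 weight per array set. Values were not centred again where part of an array set was left out. The rest of that set then keeps an offset opposite to the arrays removed, which can shift group differences in such fits.

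The calls were tested on simulated data with 22180 independent genes, 5 arrays per group and 50 genes changed at each of 4 sizes. For the mean Dex effect 31, 48, 50 and 48 of the 50 genes were called at log2 changes of 0.5, 1, 1.5 and 2, with 9 false calls among 186. For the interaction 1, 27, 39 and 43 were called, with 7 false calls among 117. A simulated Dex effect of 1 log2 in 33 genes, lowered by 0.25 log2 in Cx30GRko mice, gave an attenuation p under 0.05 in 47 of 50 sets, against 3 of 50 with no reduction. The simulated genes varied independently, so this share may be too high for real arrays, whose genes can vary together. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the figures. Values are log2 differences with their standard errors (SE) from the limma fit or group means with standard deviations (SD).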

Results

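Transcript levels were measured in the spinal cord of 20 mice, 5 per group, in a design that crossed genotype (control or Cx30GRko) with treatment (saline or Dex, 4 mg/kg, 4 h). Connexin 30 is a gap junction protein of astrocytes, and the study set out to describe the astrocyte part of the transcriptional response to the glucocorticoid receptor. Values are log2 signals of probe sets, and the number of arrays limits their precision. The arrays fell into a set of 12 (replicates 1 to 3 of each group) and a set of 8 (replicates 4 and 5), within which the values had been centred. The median residual SD of a gene was 0.21 in replicates 1 to 3 and 0.37 in replicates 4 and 5. A pair of arrays stood apart: Cx30GRko Dex replicates 4 and 5 had SDs across probe sets of 1.95 and 1.81, against 1.66 to 1.71 for the other 6 arrays of their set. Their mean correlations with the other arrays, taken across probe sets, which are not independent replicates, were 0.894 and 0.899, against 0.903 to 0.921 for those 6.

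**Figure D1:**
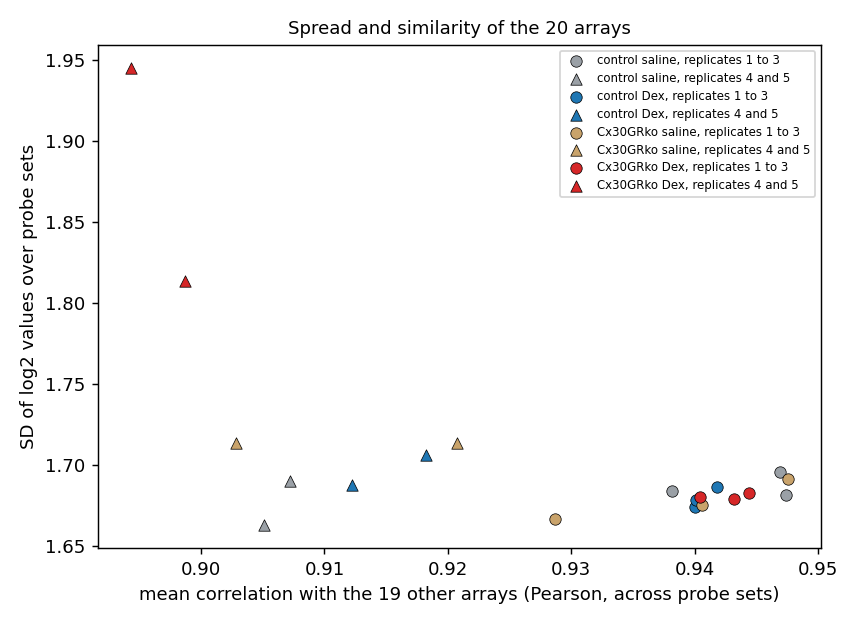
Each point is 1 of the 20 arrays, with its mean Pearson correlation with the other arrays across probe sets (horizontal axis) against the SD of its log2 values (vertical axis), coloured by group, circles for replicates 1 to 3 and triangles for replicates 4 and 5. Cx30GRko Dex replicates 4 and 5 lie at SDs of 1.95 and 1.81, above every other array.

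The first question was whether the arrays show the knockout itself. Nr3c1, the gene of the glucocorticoid receptor (probe set 17353985), had a mean signal of 6.21 ± 0.50 (SD, n = 5) in control saline, 6.22 ± 0.08 in control Dex, 6.19 ± 0.21 in Cx30GRko saline and 6.59 ± 0.70 in Cx30GRko Dex arrays. From replicate 1 to 5 the Nr3c1 values were 6.42, 6.56, 6.58, 5.39 and 6.07 in control saline, 6.30, 6.11, 6.27, 6.24 and 6.18 in control Dex, 6.49, 6.34, 6.00, 6.05 and 6.07 in Cx30GRko saline, and 6.29, 6.08, 6.17, 7.79 and 6.62 in Cx30GRko Dex arrays. The genotype difference of Nr3c1 was -0.02 ± 0.26 under saline (adjusted p = 0.995; -0.25 in replicates 1 to 3 and 0.33 in replicates 4 and 5) and 0.37 ± 0.26 under Dex (adjusted p = 0.6; -0.05 and 0.99). Gjb6, the gene of connexin 30 (probe set 17307125), had means of 6.25 ± 0.13, 6.46 ± 0.48, 6.39 ± 0.24 and 6.47 ± 0.13 in the 4 groups in the same order. From replicate 1 to 5 the Gjb6 values were 6.16, 6.46, 6.24, 6.15 and 6.23 in control saline, 6.76, 6.38, 6.29, 7.06 and 5.80 in control Dex, 6.30, 6.26, 6.43, 6.77 and 6.16 in Cx30GRko saline, and 6.44, 6.37, 6.58, 6.62 and 6.32 in Cx30GRko Dex arrays. The genotype difference of Gjb6 was 0.14 ± 0.18 under saline (adjusted p = 0.94) and 0.01 ± 0.18 under Dex (adjusted p = 0.99). These probe sets check the knockout little: whether the Nr3c1 probes lie in the removed part of the gene is unknown, and many cord cells other than astrocytes express Nr3c1.

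The second question was which genes respond to Dex in control mice. Cdkn1a, an inhibitor of cyclin-dependent kinases (probe set 17335467), rose by 1.72 ± 0.27 log2 (SE, n = 5 per group; adjusted p = 0.0181), a 3.29-fold change. Sgk3, a kinase related to the serum- and glucocorticoid-regulated kinase (probe set 17211043), rose by 1.33 ± 0.19 (adjusted p = 0.0105), 2.51-fold. Pnpla2, the adipose triglyceride lipase (probe set 17484909), rose by 0.90 ± 0.14 (adjusted p = 0.0181), 1.86-fold. Each of the 3 was above the saline mean of its array set in 5 of 5 Dex arrays, the same arrays that gave the calls. Within replicates 1 to 3 and replicates 4 and 5 the changes were 1.16 and 2.57 for Cdkn1a, 1.413 and 1.203 for Sgk3, and 1.00 and 0.75 for Pnpla2. The next 5 genes were not significant (adjusted p = 0.0822 each). Errfi1, a feedback inhibitor of the epidermal growth factor receptor, stood at 1.12 ± 0.20, Slc25a13, a mitochondrial aspartate-glutamate carrier, at 1.22 ± 0.23 and Arrdc2 at 1.12 ± 0.21. The apelin receptor gene Aplnr stood at -0.95 ± 0.18 and Fbxo32, a ubiquitin ligase subunit of muscle wasting, at -0.90 ± 0.17. Nor were Sgk1, the serum- and glucocorticoid-regulated kinase, at 0.91 ± 0.19 (adjusted p = 0.118), Fkbp5, a co-chaperone of the receptor, at 0.60 ± 0.25 (adjusted p = 0.901), Tsc22d3 at 0.24 (adjusted p = 0.942) and the clock gene Per1 at 0.31 (adjusted p = 0.942). Fkbp5 changed by 1.23 in replicates 1 to 3 and -0.35 in replicates 4 and 5.

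In control mice limma called 3 of 22180 genes, with 1144 at an unadjusted p under 0.05. The count was 3 with a block for the array set, 38 in replicates 1 to 3 (30 higher, 8 lower) and 0 in replicates 4 and 5 (1030 at an unadjusted p under 0.05). It was 7 without Cx30GRko Dex replicates 4 and 5, and these 4 fits were chosen after the data were seen. The count was 0 with a replicate block, with only the groups compared or at an adjusted p under 0.01, and 1 (Sgk3) with all probe sets kept. With array weights it was 58. No gene was called without control Dex replicate 1 or 4. Sgk3 alone was called without control Dex replicate 2, and 5 genes were called without Cx30GRko Dex replicate 5, with Errfi1 and Nt5c3 (0.97) gained (adjusted p = 0.0428 each). Cdkn1a also lost its call without control saline replicate 1 (adjusted p = 0.0666) or control Dex replicate 5 (0.0525). Pnpla2 lost its call without control saline replicate 1, 2, 3 or 4 (0.0732, 0.0801, 0.0751 and 0.0793) or control Dex replicate 3 (0.0595). Calls of falls were gained by Mup3, a major urinary protein gene, without control saline replicate 1 (-2.19, adjusted p = 0.00361), Fbxo32 without control saline replicate 5 (-1.07, 0.0117) and Aplnr without control Dex replicate 3 (-1.06, 0.044). Calls of rises were gained by Slc25a13 without control Dex replicate 5 (1.43, 0.00878) or Cx30GRko Dex replicate 3 (0.0215), Dusp18 without control Dex replicate 5 (1.06, 0.0356), Sgk1 without Cx30GRko saline replicate 3 (0.027) and Arrdc2 without Cx30GRko Dex replicate 4 (0.0425). Mup3, Dusp18 and Nt5c3 are named here after their values were seen.

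The glucocorticoid receptor targets, genes widely induced by the hormone, were shifted up as a group in control mice, with a median of 0.62 and 28 of 30 measured members higher (adjusted p = 1.92e-28; 8.8e-05 with an estimated correlation). Its member Cdkn1a rose when adjusted over all genes, and 19 rose adjusted over the list alone. The median of the targets was 0.71 in replicates 1 to 3 and 0.26 in replicates 4 and 5. Hif3a, a hypoxia-inducible factor subunit of this list, stood at 1.36 ± 0.28 (adjusted p = 0.105). Markers of meningeal fibroblasts were shifted down (12 measured, median -0.46, adjusted p = 0.000121; adjusted p = 0.368 with an estimated correlation; -0.64 and -0.31 in the 2 sets). So were markers of Schwann cells and peripheral roots (8 measured, -0.62, 0.000761; 0.368 with an estimated correlation; -0.80 and -0.14) and of endothelial cells (19 measured, -0.17, 0.00143; 0.368 with an estimated correlation; -0.26 and -0.16). No member of these 3 lists passed the test, in all genes or adjusted over the list alone. Members with the smallest p were the matrix proteoglycan genes Ogn (-2.29 ± 0.81) and Dcn (-1.34 ± 0.56). They also included the peripheral myelin genes Pmp22 at -0.93 ± 0.41 and Pmp2 at -0.98 ± 0.60, and the vascular receptor genes Kdr at -0.73 ± 0.27 and Tek at -0.63 ± 0.25. Neuron markers were shifted up (19 measured, 0.18, adjusted p = 0.0059; adjusted p = 0.423 with an estimated correlation; 0.07 and 0.32), and no member passed. The smallest p were those of Gad2, an enzyme of GABA synthesis, at 0.47 ± 0.21 and Snap91 at 0.54. Markers of neutrophils and blood monocytes were shifted down (15 measured, -0.12, adjusted p = 0.0103; adjusted p = 0.368 with an estimated correlation; -0.04 and -0.21), with the calprotectin gene S100a9 at -0.40 ± 0.18. The neuron call was lost without control saline replicate 4 (0.174) or control Dex replicate 3 (0.0506), and the neutrophil call without control saline replicate 3 (0.0512) or 4 (0.0646) or control Dex replicate 1 (0.0939).

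The same question was asked in Cx30GRko mice. Cdkn1a rose by 1.88 ± 0.27 (SE, n = 5 per group; adjusted p = 0.0129), 3.67-fold, and Slc25a13 (probe set 17464672) by 1.52 ± 0.23 (adjusted p = 0.0129), 2.87-fold. Sgk1 (probe set 17232055) rose by 1.11 ± 0.19 and Sgk3 by 1.10 ± 0.19 (adjusted p = 0.0403 for both). Each was above the saline mean of its array set in 5 of 5 Dex arrays, the same arrays that gave the calls. The next genes were not significant: Zbtb16, a zinc finger transcription factor, at 1.42 ± 0.25 (adjusted p = 0.0613), the metallothionein gene Mt2 at 0.85 ± 0.16 (0.0952) and Arrdc2 at 1.11 (0.109). They were followed by the interleukin 6 receptor gene Il6ra at 0.94 ± 0.19 (0.155) and the nucleotidase gene Nt5c3 at 0.99 ± 0.20 (0.189). Fkbp5 stood at 0.78 ± 0.25 (adjusted p = 0.47; 1.14 in replicates 1 to 3, 0.24 in replicates 4 and 5), Tsc22d3 at 0.43 (0.47) and Per1 at 0.65 (0.458). Cdkn1a and Sgk3 were called in both genotypes, against 0.000541 genes expected to be shared if the calls were independent. They are not fully so, since both effects rest on the same estimate of each gene's spread, and this number is therefore too low a baseline. With a block for the array set Sgk1 and Sgk3 lost their calls in Cx30GRko mice (adjusted p = 0.0737 each), so that Cdkn1a was the 1 gene called in both genotypes.

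In Cx30GRko mice limma called 4 genes, with 2158 at an unadjusted p under 0.05. The count was 2 with a block for the array set (Cdkn1a and Slc25a13, adjusted p = 0.0243 each), 7 in replicates 1 to 3 (6 higher, 1 lower), 0 in replicates 4 and 5 (2917 at an unadjusted p under 0.05) and 0 without Cx30GRko Dex replicates 4 and 5. It was 0 with a replicate block, with all probe sets kept or at an adjusted p under 0.01, and 1 (Cdkn1a) with only the groups compared. With quantile normalization again or cyclic loess it was 2, and with array weights 18. No gene was called without Cx30GRko Dex replicate 5, where Cdkn1a had an adjusted p of 0.0606. Cdkn1a alone was called without Cx30GRko saline replicate 1 or 5 or Cx30GRko Dex replicate 1 or 2. Cdkn1a and Slc25a13 alone were called without control saline replicate 1, 2 or 3, control Dex replicate 1, 2, 3 or 4, Cx30GRko saline replicate 2 or Cx30GRko Dex replicate 3. Of the other calls, Sgk3 was lost without Cx30GRko saline replicate 3 (adjusted p = 0.08), and Sgk1 without control Dex replicate 5 (0.0589), Cx30GRko saline replicate 4 (0.0589) or Cx30GRko Dex replicate 4 (0.0567). Calls were gained by Zbtb16 without control saline replicate 4 (adjusted p = 0.0364) or 5 (0.0117), Arrdc2 without Cx30GRko Dex replicate 4 (0.0231) and Errfi1, named here after its values were seen, without control saline replicate 5 (0.034).

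The glucocorticoid receptor targets were shifted up in Cx30GRko mice as well, with a median of 0.65 and 30 of 30 members higher (adjusted p = 1.1e-22; 0.000342 with an estimated correlation; 0.70 in replicates 1 to 3, 0.27 in replicates 4 and 5). Among them Cdkn1a and Sgk1 rose when adjusted over all genes, and 18 rose adjusted over the list alone. A further 5 lists were shifted up with the preset correlation but not with an estimated one. Astrocyte markers had a median of 0.27 (25 measured, adjusted p = 1.11e-05; adjusted p = 0.474 with an estimated correlation; 0.03 and 0.64 in the 2 sets), with 1 member rising adjusted over the list alone and Mlc1, an astrocyte membrane protein gene, at 0.74 ± 0.25. Genes of glucose, glycogen and lactate metabolism had a median of 0.27 (21 measured, 0.000661; 0.474 with an estimated correlation; 0.08 and 0.52), with 2 rising adjusted over the list alone and the glucose transporter gene Slc2a1 at 0.91 ± 0.20 (0.238). Genes of glutamate, potassium and amino acid handling had a median of 0.24 (15 measured, 0.00619; 0.474 with an estimated correlation; -0.00 and 0.81), with the potassium channel gene Kcnj10 at 0.56 ± 0.19. Genes of cholesterol synthesis had a median of 0.33 (16 measured, 0.0129; 0.474 with an estimated correlation; 0.01 and 0.82), with Hsd17b7 at 0.56 ± 0.17. The fifth list was the receptor machinery, with a median of 0.25 (11 measured, 0.041; 0.474 with an estimated correlation; 0.03 and 0.42), with the coactivator gene Ncoa1 at 0.45 ± 0.23. None of the 5 was called without Cx30GRko Dex replicates 4 and 5 (adjusted p = 0.135, 0.076, 0.535, 0.626 and 0.392 in the order given), the arrays that stood apart, whose mean astrocyte marker scores of 0.71 and 0.39 were the highest of all arrays. Leaving out Cx30GRko Dex replicate 4 alone ended the calls of the glutamate list (0.276), the cholesterol list (0.178) and the machinery (0.276), and the machinery was also lost without Cx30GRko saline replicate 2 (0.0843) or 4 (0.0871).

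The mean of both Dex effects asked which genes respond to Dex across genotypes, and 33 genes did (29 rose, 4 fell; n = 10 Dex and 10 saline arrays). The largest rises were those of Cdkn1a (1.80 ± 0.19, adjusted p = 7.64e-05), Ccng1, a cyclin (1.49 ± 0.26, 0.0115), Slc25a13 (1.37 ± 0.16, 0.000185), Setdb2, of the histone methyltransferase family (1.26 ± 0.24, 0.0293), and Sgk3 (1.22 ± 0.13, 7.64e-05). They were followed by Zbtb16 (1.19 ± 0.18, 0.00268), Hif3a (1.13 ± 0.19, 0.0115), Arrdc2 (1.11 ± 0.15, 0.000919), Errfi1 (1.02 ± 0.15, 0.00154) and Sgk1 (1.01 ± 0.13, 0.000744). The 4 that fell were Gbp11, a guanylate-binding protein gene (-0.77 ± 0.15, 0.0285), Fbxo32 (-0.68 ± 0.12, 0.0162), the keratin gene Krt78 (-0.65 ± 0.13, 0.0485) and Aplnr (-0.62 ± 0.12, 0.0428). In all 10 Dex arrays 24 of the 33 genes lay on the side of their mean effect, and all 33 did so in at least 8. The genes were chosen for that effect on the same arrays, so these counts are no independent check. Fkbp5 (0.69 ± 0.18, adjusted p = 0.214), Tsc22d3 (0.33 ± 0.09, 0.326) and Per1 (0.48 ± 0.14, 0.326) did not pass, and were above the saline mean in 7, 9 and 9 of 10 Dex arrays.

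**Figure D2:**
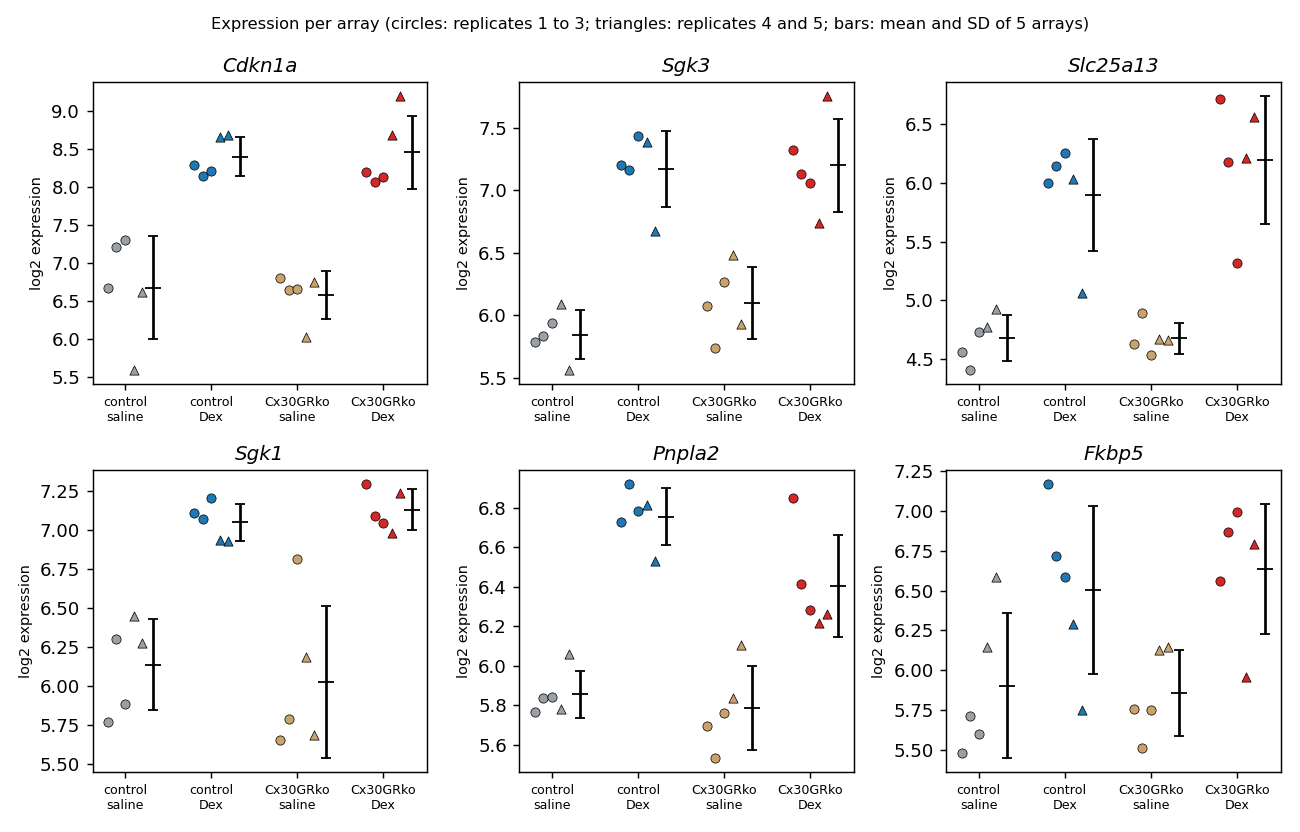
Log2 signal (vertical axis) of Cdkn1a, Sgk3, Slc25a13, Sgk1, Pnpla2 and Fkbp5 on each array of the 4 groups (horizontal axis), circles for replicates 1 to 3 and triangles for replicates 4 and 5, with bars for the mean and SD of 5. Group means of Cdkn1a were 6.68 and 6.58 under saline and 8.40 and 8.46 under Dex in control and Cx30GRko mice.

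Within the array sets the mean Dex effect of Cdkn1a was 1.29 in replicates 1 to 3 and 2.56 in replicates 4 and 5, and that of Ccng1 0.79 and 2.54. The order was the opposite for Setdb2 (1.85 and 0.39) and Fkbp5 (1.18 and -0.05). Ddit4, an inhibitor of mTOR signalling, rose by 0.83 ± 0.16 over all arrays (adjusted p = 0.0285), with 1.32 and 0.10 in the sets. In limma 1916 genes had an unadjusted p under 0.05. The count of 33 became 24 with a block for the array set (22 higher, 2 lower; 24 of them among the 33), and 101 in replicates 1 to 3 (79 higher, 22 lower; 25 of them among the 33). With the block Aplnr (adjusted p = 0.0712) and Krt78 (0.0791) were no longer called among the falls, and Plin4 (0.056) and Mt1 (0.0692) were no longer called among the receptor targets. The count was 0 in replicates 4 and 5 (2224 at an unadjusted p under 0.05), and 24 without Cx30GRko Dex replicates 4 and 5 (22 among the 33). A replicate block left 15 genes, all probe sets left 20, and 13 had an adjusted p under 0.01. Array weights gave 129. It was 21 and 19 without control saline replicates 1 and 2, 19, 18 and 20 without control Dex replicates 1, 2 and 3, and 20 without Cx30GRko saline replicate 2. Of the 33 genes 18 were called in all 20 fits that left out 1 array.

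Among the glucocorticoid receptor targets 10 of 30 members rose across genotypes, 26 adjusted over the list alone, and 29 were higher (median 0.57, adjusted p = 4.62e-39; 1.16e-05 with an estimated correlation; 0.74 in replicates 1 to 3, 0.34 in replicates 4 and 5). The 10 were Cdkn1a, Sgk1, Arrdc2, Errfi1, Zbtb16, Hif3a, Ddit4, the lipid droplet gene Plin4 (0.94 ± 0.18, adjusted p = 0.0344) and the metallothionein genes Mt1 (0.48 ± 0.09, 0.0359) and Mt2 (0.75 ± 0.11, 0.00268). Astrocyte markers were shifted up (25 measured, median 0.20, adjusted p = 2.17e-05; adjusted p = 0.401 with an estimated correlation; 0.04 and 0.44 in the 2 sets). None of them passed over all genes and 1 passed adjusted over the list alone, with the smallest p for Ppp1r3c, a glycogen-targeting phosphatase subunit (0.63 ± 0.13, 0.0559), and S100b at 0.58 ± 0.22. Without Cx30GRko Dex replicates 4 and 5 the astrocyte median was 0.11 (adjusted p = 0.0223). The values were not centred again for this fit, so the other arrays of that set keep an offset from the removed pair. This call is therefore not free of the pair, and replicates 1 to 3 alone gave the 0.04 above. In the glucose list Slc2a1 rose (0.73 ± 0.14, adjusted p = 0.0285), 2 members passed adjusted over the list alone, and the list was shifted up (21 measured, 0.17, 0.000193; adjusted p = 0.366 with an estimated correlation; 0.12 and 0.29).

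Smaller shifts across genotypes were seen in 4 more lists, none with a member that passed over all genes. Neuron markers had a median of 0.17 (19 measured, adjusted p = 0.00382; adjusted p = 0.551 with an estimated correlation; -0.01 and 0.47 in the 2 sets), with the glycine transporter gene Slc6a5 at 0.51 ± 0.17. Genes of glutamate, potassium and amino acid handling had a median of 0.17 (15 measured, 0.0216; adjusted p = 0.61 with an estimated correlation; 0.03 and 0.42), with Glul, glutamine synthetase, at 0.25 ± 0.11. The receptor machinery stood at 0.14 (11 measured, 0.0316; 0.00 and 0.27), with 1 member passing adjusted over the list alone, and the neutrophil and blood monocyte markers at -0.13 (15 measured, 0.0316; -0.06 and -0.13). For both of these the adjusted p = 0.366 with an estimated correlation. None of the 4 was called without Cx30GRko Dex replicates 4 and 5 (adjusted p = 0.204, 0.423, 0.182 and 0.1). Without single arrays the glutamate list was lost for control saline replicate 4 (0.0988), control Dex replicate 1 (0.0552) and Cx30GRko Dex replicate 4 (0.219). The machinery was lost for control saline replicate 5 (0.0539), control Dex replicate 1 (0.0712), Cx30GRko saline replicates 2 (0.0579) and 4 (0.062) and Cx30GRko Dex replicate 4 (0.132). The neutrophil list was lost for control saline replicates 3 (0.0824) and 4 (0.0988), control Dex replicates 1 (0.0939) and 5 (0.0655), Cx30GRko saline replicates 2 (0.0579) and 4 (0.0609) and Cx30GRko Dex replicates 2 (0.058) and 4 (0.0881).

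The other 18 lists had no call across genotypes. In the lipid droplet and fatty acid oxidation list Pnpla2 (0.76 ± 0.10, adjusted p = 0.000744) and Plin4 rose, also adjusted over the list alone, and the median of its 16 members was 0.12 (0.063). Medians were 0.15 for heat shock and chaperones (0.063), -0.07 for endothelial markers (0.207), and -0.06 for NF-kB and inflammatory genes (0.25). They were -0.08 for skeletal muscle (0.305), -0.07 for immediate early genes (0.323), -0.11 for meningeal fibroblasts (0.452), -0.04 for lymphocytes (0.474), 0.08 for cholesterol synthesis (0.494) and -0.09 for Schwann cells (0.494). They were 0.10 for ependymal cells (0.514), -0.03 for microglia (0.514), -0.04 for oligodendrocyte precursors (0.514), 0.07 for oligodendrocytes (0.533), 0.04 for the circadian clock (0.778), with 1 member passing adjusted over the list alone, and 0.01 for the 3 measured erythrocyte genes (0.778). Mural cell markers had a median of 0.00, a mean of -0.03 and a test direction of down (0.618), and reactive astrocyte genes a median of 0.04, a mean of 0.02 and a direction of down (0.86).

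The central question was whether the Dex response differs between Cx30GRko and control mice. Over the 33 Dex genes the summed effect in Cx30GRko mice was 0.955 of that in control mice, and 18 of the 33 had a smaller effect there. The median signed difference was -0.08 log2 (exact two-sided permutation p = 0.355), with -0.08 for the 29 rising genes (16 smaller, exact p = 0.392) and -0.10 for the 4 falling genes (exact p = 0.467). The most similar effects were those of Arrdc2 (difference -0.0062), Nt5c3 (0.0134), Ppp2r3a (0.0495), Hipk1 (0.0649) and Ccdc141 (-0.0791). The smallest p among the 33 was that of Aplnr, at -0.95 in control mice with a difference of 0.67 ± 0.25 (adjusted p = 0.424 over the Dex genes), and none was called. The next were Il6ra at 0.56 ± 0.27, Dusp18 at -0.50 ± 0.26 and Fbxo32 at 0.45 ± 0.24 (adjusted p = 0.638 each). Krt78 at -0.40 ± 0.27, Pnpla2 at -0.28 ± 0.20, Tma16 at 0.46 ± 0.34, Fam214a at -0.25 ± 0.19, Slc2a1 at 0.35 ± 0.28 and Zbtb16 at 0.45 ± 0.36 followed (0.722 each). Within replicates 1 to 3 the median signed difference over the 33 genes was -0.15 (exact p = 0.205) and within replicates 4 and 5 it was 0.08 (exact p = 0.833). The alternatives that follow used the genes called in their own fit instead of the 33. Over the 24 genes called with a block for the array set the median signed difference was -0.10 (exact p = 0.346). Over the 24 called without Cx30GRko Dex replicates 4 and 5 it was -0.17 (exact p = 0.192). With quantile normalization again it was -0.22, with a ratio of summed effects of 0.883 (exact p = 0.0449), and with dim genes left out it was 0.00 (0.0036, exact p = 0.971). Over the 3 genes called in control mice it was -0.23 (exact p = 0.184) and over the 4 called in Cx30GRko mice 0.17 (exact p = 0.369), choices that each favour their own genotype. Without Cx30GRko Dex replicate 5 it was -0.18 over the 23 genes called, and without Cx30GRko Dex replicate 3 it was -0.01 over 26.

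**Figure D3:**
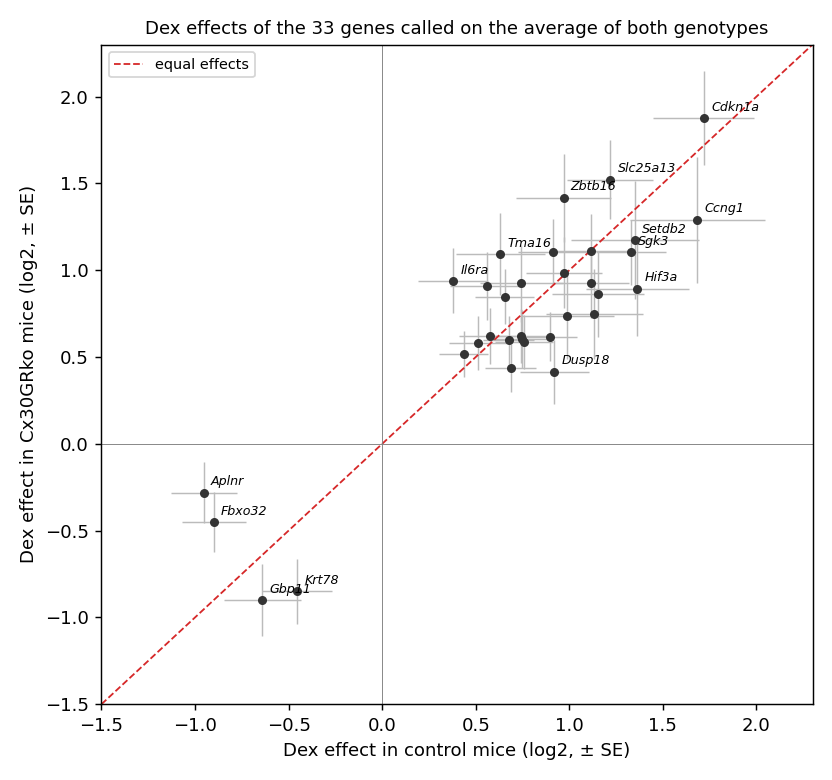
Log2 Dex effect in control mice (horizontal axis) against that in Cx30GRko mice (vertical axis) for the 33 Dex genes, with bars for the SE and a dashed line where both are equal. Cdkn1a lies at 1.72 and 1.88, and Aplnr at -0.95 in control mice.

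Over all 22180 genes limma called 0 for the difference between the Dex effects, with 1253 at an unadjusted p under 0.05 and a smallest adjusted p of 0.604. The count was also 0 with a block for the array set, in replicates 1 to 3 (1170 at an unadjusted p under 0.05) and in replicates 4 and 5 (1636). The 5 genes with the smallest p were not significant. 1700018F24Rik stood at -1.36 ± 0.26, Mup3 at 2.41 ± 0.49 and Tmem189 at 1.71 ± 0.35 (adjusted p = 0.604 each). The matrix metalloproteinase gene Mmp7 stood at 1.49 ± 0.33 and the odorant receptor gene Olfr372 at -1.40 ± 0.32 (0.846 each). Mup3 differed by 1.47 in replicates 1 to 3 and 3.82 in replicates 4 and 5, and without control saline replicate 1 it was the 1 gene called (2.79, adjusted p = 0.0117).

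The receptor targets as a group had a median difference of 0.16 between the Dex effects (adjusted p = 0.715). Markers of meningeal fibroblasts and of Schwann cells and peripheral roots, which were lower after Dex in control mice, differed most: their median differences were 0.81 (adjusted p = 3.5e-05; adjusted p = 0.384 with an estimated correlation; 1.06 and 0.57 in the 2 sets) and 0.91 (0.000203; 0.384 with an estimated correlation; 1.12 and 0.66). Cholesterol synthesis followed at 0.34 (0.00141; 0.15 and 0.72) and endothelial markers at 0.41 (0.00857; 0.20 and 0.57), both with an adjusted p = 0.384 with an estimated correlation. Astrocyte markers differed by 0.18 (0.0468; -0.04 and 0.49; adjusted p = 0.581 with an estimated correlation). No member of the 5 lists passed the test. The smallest p were those of Ogn at 3.39 ± 1.14 and Dcn at 2.10 ± 0.79 among the meningeal markers, and of Pmp22 at 1.54 ± 0.59 and Egr2, a transcription factor of Schwann cell myelination, at 1.15 ± 0.55, among the Schwann cell markers. In the other lists they were those of Srebf2, which drives sterol synthesis genes, at 0.91 ± 0.32, Vwf, the von Willebrand factor gene, at 0.60 ± 0.27 and Mlc1 at 0.65 ± 0.36. Mean meningeal marker scores ranged from -1.04 in control Dex replicate 3 to 0.97 in Cx30GRko Dex replicate 3. The calls of these 2 marker lists for Dex in control mice, for the interaction and for genotype under saline all use the control saline arrays. They are therefore not independent of each other. In replicates 1 to 3 the mean score of both lists together was 0.397 in control saline, -0.295 in control Dex, -0.187 in Cx30GRko saline and 0.086 in Cx30GRko Dex arrays. With a block for the array set the 5 lists kept their calls. Without Cx30GRko Dex replicates 4 and 5 the meningeal (1.15e-05) and Schwann cell (5.22e-05) calls stayed and the cholesterol (0.0952), endothelial (0.0612) and astrocyte (0.997) calls were lost. Of single arrays, Cx30GRko Dex replicate 4 ended the endothelial call (0.114). The astrocyte call was lost without control saline replicates 1, 2 or 3 (0.117, 0.0927, 0.116), control Dex replicates 1 or 5 (0.0511, 0.163), Cx30GRko saline replicates 2, 4 or 5 (0.0636, 0.0705, 0.126) or Cx30GRko Dex replicates 4 or 5 (0.524, 0.0938).

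The effect of the genotype without the agonist was asked under saline. The gene with the smallest p, Mup3 (probe set 17426097), was not significant at -1.92 ± 0.35 (SE, n = 5 per group; adjusted p = 0.343; -1.56 in replicates 1 to 3, -2.47 in replicates 4 and 5). The Mup3 means were 5.21 ± 1.04 (SD) in control saline, 3.40 ± 0.55 in control Dex, 3.28 ± 0.17 in Cx30GRko saline and 3.88 ± 0.32 in Cx30GRko Dex arrays. All 5 Cx30GRko saline arrays were below the lowest control saline array (3.52 at most, against 3.69). Twist1, a mesenchymal transcription factor, at -0.85 ± 0.18, the neuropeptide Y receptor gene Npy2r at 1.11 ± 0.24, Imp3 at -0.72 ± 0.16 and Evc2, of cilia, at -0.78 ± 0.18 came next (adjusted p = 0.914 each). In limma 0 genes were called, with 1165 at an unadjusted p under 0.05, and 0 also in replicates 1 to 3 (1262), in replicates 4 and 5 (1181) and with a block for the array set. Without control saline replicate 1 Mup3 was called (-2.30, adjusted p = 0.00164).

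The receptor targets had a median genotype difference of -0.05 under saline (adjusted p = 0.273). Markers of meningeal fibroblasts were shifted down in Cx30GRko mice (median -0.39, adjusted p = 0.000989; adjusted p = 0.518 with an estimated correlation; -0.50 and -0.34 in the 2 sets), with Ogn at -1.71 ± 0.81 and the collagen gene Col1a2 at -0.91 ± 0.44. Schwann cell and root markers were shifted down as well (-0.62, 0.00163; 0.518 with an estimated correlation; -0.54 and -0.32), with Egr2 at -0.96 ± 0.39 and the claudin gene Cldn19 at -0.85 ± 0.40. So were neutrophil and blood monocyte markers (-0.20, 0.00273; 0.335 with an estimated correlation; -0.18 and -0.22), with the calprotectin genes S100a9 at -0.48 ± 0.18 and S100a8 at -0.63 ± 0.25. Skeletal muscle markers followed (10 measured, -0.32, 0.029; 0.518 with an estimated correlation; -0.19 and -0.34), with myoglobin, Mb, at -0.69 ± 0.33. Neuron markers were shifted up (0.14, 0.00907; 0.518 with an estimated correlation; 0.10 and 0.26), with the synaptotagmin gene Syt1 at 0.64 ± 0.28. No member of these 5 lists passed the test. The meningeal, Schwann cell, neutrophil and neuron lists were also called for Dex in control mice, in the same directions. Both comparisons use the same control saline arrays, so these calls are not independent. The neuron call was lost without control saline replicate 4 (0.216), the Schwann cell call without control saline replicate 3 (0.0609), and the skeletal muscle call without control saline replicate 2 (0.432) or 5 (0.13) or Cx30GRko saline replicate 2 (0.0875) or 4 (0.061).

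The genotype effect after Dex completed the design. The 5 genes with the smallest p were not significant (adjusted p = 0.423 each): Olfr1342 at 0.70 ± 0.15 (SE, n = 5 per group), the phosphatase gene Dusp18 at -0.86 ± 0.18, the sulfotransferase gene Sult1c1 at -1.07 ± 0.23, Nat9 at -0.74 ± 0.16 and Sdcbp2 at -0.74 ± 0.16. In limma 0 genes were called, with 2481 at an unadjusted p under 0.05, and 0 also in replicates 1 to 3 (1061), in replicates 4 and 5 (3230), with a block for the array set and without Cx30GRko Dex replicates 4 and 5. The receptor targets had a median difference of -0.01 (adjusted p = 0.571), and 1 member passed adjusted over the list alone. In this list the kinase gene Pim3 stood at -0.80 ± 0.18 (0.423) and the transcription factor gene Klf9 at 0.59 ± 0.24.

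After Dex, astrocyte markers were shifted up in Cx30GRko mice (median 0.26, adjusted p = 0.00188; adjusted p = 0.536 with an estimated correlation; -0.01 and 0.41 in the 2 sets), with the water channel gene Aqp4 at 0.46 ± 0.15 and the connexin 43 gene Gja1 at 0.55 ± 0.18. Genes of cholesterol synthesis (0.34, 0.00188; 0.536 with an estimated correlation; 0.02 and 0.76), with Sc5d at 0.73 ± 0.29, and of glutamate, potassium and amino acid handling (0.38, 0.00233; 0.536 with an estimated correlation; 0.01 and 0.83), with the glutamate transporter gene Slc1a3 at 0.68 ± 0.29, were shifted up too. So were markers of oligodendrocytes (16 measured, 0.27, 0.0174; 0.536 with an estimated correlation; 0.01 and 0.57), with the myelin gene Mag at 0.69 ± 0.28. No member of these 4 lists passed the test. The shifts came with the arrays that stood apart: without Cx30GRko Dex replicates 4 and 5 none of the 4 lists was called (adjusted p = 0.556, 0.223, 0.434 and 0.499). Leaving out Cx30GRko Dex replicate 4 alone ended the calls of the astrocyte (0.178), glutamate (0.178) and oligodendrocyte (0.292) lists, and control Dex replicate 5 that of the oligodendrocyte list (0.0509).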

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

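The tests of a Dex response, of noise and of the signal range as the source of the distant arrays, and the fits without these arrays, were chosen only after the result was seen.

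The interaction test with the preset correlation called 5 gene lists, none of which was called with an estimated correlation (adjusted p = 0.581 for the astrocyte markers and 0.384 for the other 4). The median differences were 0.9086 log2 for Schwann cell and peripheral root markers, 0.8055 for meningeal fibroblast markers, 0.4074 for endothelial markers, 0.3366 for cholesterol synthesis and 0.1779 for astrocyte markers. The camera calls of the endothelial, cholesterol and astrocyte lists ended without Cx30GRko Dex replicates 4 and 5 (0.0612, 0.0952 and 0.997).

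Outside the genes with 1 symbol, 1 of 17824 probe sets responded to Dex across genotypes when all probe sets were tested, and 1348 had an unadjusted p under 0.05. Probe set 17209895, which had no gene symbol, differed by -1.569 (adjusted p = 0.024). Its means were 4.71 ± 0.30 (SD, n = 5) in control saline, 3.27 ± 0.87 in control Dex, 5.09 ± 0.69 in Cx30GRko saline and 3.38 ± 0.53 in Cx30GRko Dex arrays.

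Single arrays far from the other 4 of their group, by a gap above 0.71 of the group's range, were found in 34 of 360 groups of 5 values (88 named genes and 2 array measures in 4 groups). Chance gives about 1 in 20 groups if the 5 values are independent and equally spread. Here each group joins 2 array sets of unequal spread, and all genes share the same arrays. The 1 in 20 is therefore too low a baseline, and no excess can be read from the count. Replicates 4 and 5, the array set with the larger spread, supplied 29 of the 34. In control saline arrays these were Egr2 at 5.913 in replicate 1 and Gjb6 at 6.463 in replicate 2. In control saline replicate 4 they were Aqp4 at 8.302, Krt78 at 5.246, Snap91 at 6.266 and Syt1 at 6.624, and in replicate 5 Errfi1 at 5.994, Pnpla2 at 6.06, Setdb2 at 6.501 and Slco1c1 at 5.965. In control Dex arrays they were Col1a2 at 5.253 in replicate 3, Ccng1 at 8.797, Fam214a at 7.021 and Glul at 9.545 in replicate 4, and Aqp4 at 8.373, Kcnj10 at 7.527, Slc25a13 at 5.061 and Slc2a1 at 7.927 in replicate 5.

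In Cx30GRko saline arrays the distant values were Vwf at 3.963 in replicate 3 and, in replicate 4, Ccng1 at 6.513, Cdkn1a at 6.033, Ncoa1 at 7.141, Ppp1r3c at 5.29, S100a9 at 3.148 and Slc6a5 at 7.018. In replicate 5 of that group they were Olfr372 at 2.278, Slc1a3 at 5.953 and Zbtb16 at 5.542. In Cx30GRko Dex arrays they were Col1a2 at 5.249 in replicate 1, Fbxo32 at 6.307, Slco1c1 at 8.223, Tnfaip6 at 8.191 and Trim59 at 7.381 in replicate 4, and Nfkbia at 7.465 in replicate 5. The SD of log2 values and the mean correlation with the other arrays gave no distant array in any group. The gap rule looks for a single array and can miss 2 that lie apart together, as Cx30GRko Dex replicates 4 and 5 did.

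Cx30GRko Dex replicates 4 and 5 stood apart from the other 6 arrays of their set. A response of Cx30GRko mice to Dex would recur in replicates 1 to 3, but the group's deviation from the other groups correlated at 0.013 across genes between the sets. This argues at most against a response shared by many genes. A response of few genes could not be seen this way, since the Dex effects of the 2 genotypes themselves correlated at only 0.117 across all genes. Noise that is independent between the arrays of the set is argued against by what the pair shared: after quantile normalization their deviations from the other 6 arrays correlated at 0.446 across probe sets, against at most 0.313 for the other 27 pairs of the set (SD 0.089). A wider signal range left by the normalization could not be told apart from other sources: equal ranges lowered the SDs of their deviations from 0.822 and 0.726 to 0.711 and 0.69, both still above the highest of the other 6 (0.661), the first by more and the second by less than the SD of those 6 (0.041). What the pair shared stays open, and a difference between the animals or in the handling of their RNA may lie behind it, neither of which was tested.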

How the results depend on the processing

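The block for the array set, the fits to each array set alone, the fit without Cx30GRko Dex replicates 4 and 5 and the weight per array set were chosen only after the data were seen. Fits that left out part of an array set kept the centring made with all of its arrays. The spread between arrays limits what could be called: the median residual SD was 0.21 in replicates 1 to 3 and 0.37 in replicates 4 and 5. Of the values of single named genes under the alternatives, 6963 kept their direction and side of the threshold, 213 lost a call, 66 gained one, 111 turned direction without a call and 0 reversed. For single lists 737 stayed, 149 lost their call, 5 turned direction without a call and 0 reversed. The interaction among the Dex genes stayed at 0 in all 34 alternatives, and genotype under Dex at 0 genes in every fit that left out 1 array. The cause was not tested for any change below, except that subsets hold fewer arrays and a stricter threshold passes fewer genes.

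Counts of called genes are given in the order Dex in control mice, Dex in Cx30GRko mice, both averaged. They were 3, 4 and 33 as reported. They were 0, 0 and 15 with a replicate block (14 of the 15 among the 33), 1, 0 and 20 with all probe sets tested, 58, 18 and 129 with array weights, and 0, 0 and 13 at an adjusted p under 0.01. They were 38, 7 and 101 in replicates 1 to 3, 0, 0 and 0 in replicates 4 and 5 (limma; 1030, 2917 and 2224 at an unadjusted p under 0.05), 7, 0 and 24 without Cx30GRko Dex replicates 4 and 5, and 49, 13 and 114 with 1 weight per array set. With array weights all 33 genes were among the 129, and with 1 weight per set all 33 were among the 114. Fitting only the groups compared gave 0 in control and 1 in Cx30GRko mice. In Cx30GRko mice the count was 2 with quantile normalization again, 2 with cyclic loess and 2 with the block for the array set. Leaving out 1 array gave 0 to 5 genes in control mice, 0 to 6 in Cx30GRko mice, 18 to 35 for both averaged, 0 to 1 for the interaction and 0 to 1 for genotype under saline. The low ends came without control Dex replicate 1 or 4, without Cx30GRko Dex replicate 5 and without control Dex replicate 2, and the single calls were Mup3 without control saline replicate 1.

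Each alternative measured the attenuation over the genes called in its own fit, so the genes changed along with the values. The attenuation of -0.0791 became 0.0036 over 28 genes with dim genes left out (exact p = 0.971) and -0.2184 over 29 genes with quantile normalization again (exact p = 0.0449). It became 0.1743 over the 4 genes called in Cx30GRko mice (exact p = 0.369). Over the 3 genes called in control mice it was -0.2262 (exact p = 0.184), and both choices favour their own genotype. It was -0.0791 over the 15 genes called with a replicate block (exact p = 0.524) and ranged from -0.176 to -0.0085 with 1 array left out. The other 33 alternatives with a value kept its direction and side of the threshold. Replicates 4 and 5 alone called no Dex gene to measure it over, and over the 33 genes of all arrays they turned its direction (0.0782, exact p = 0.833).

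Gene lists called, in the order control Dex, Cx30GRko Dex, interaction, genotype under saline, genotype under Dex and Dex averaged, numbered 6, 6, 5, 5, 4 and 7. With an estimated correlation they numbered 1, 1, 0, 0, 0 and 1, and with fry 1, 1, 0, 0, 0 and 1, the receptor targets in each case. In replicates 1 to 3 they numbered 10 for control Dex, 2 for Cx30GRko Dex, 9 for the interaction and 1 for genotype under Dex. In replicates 4 and 5 they numbered 3 for control Dex and 7 for genotype under Dex. Without Cx30GRko Dex replicates 4 and 5 they numbered 1 for Cx30GRko Dex, 0 for genotype under Dex and 4 for Dex averaged. With 1 array left out they ranged from 5 to 10 for control Dex, 3 to 9 for Cx30GRko Dex, 3 to 7 for the interaction, 1 to 9 for genotype under Dex and 4 to 9 for Dex averaged. Counts moved by over 1.5 times for control Dex without control Dex replicate 5 (10), for Cx30GRko Dex and the interaction without Cx30GRko Dex replicate 4 (3 each) and for Dex averaged without control Dex replicate 1 (4). For genotype under Dex they did so without Cx30GRko Dex replicate 4 (1), control Dex replicates 1 (9) and 2 (7), and Cx30GRko Dex replicates 1 (8), 3 (7) and 5 (8).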

Other observations

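The tests of a larger spread and of the receptor targets in replicates 4 and 5, the regroupings over the Dex genes of replicates 1 to 3, the splits for the receptor targets and for the interaction among the Dex genes, and the results within each array set were chosen only after the result was seen.

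In replicates 1 to 3 alone 101 genes responded to Dex across genotypes (n = 6 Dex and 6 saline arrays), 25 of them among the 33 of all arrays. The largest rises were those of Setdb2 (1.85 ± 0.15 log2, SE), Hif3a (1.497 ± 0.21), Slc25a13 (1.48 ± 0.19), Zfp36, which speeds the decay of inflammatory transcripts (1.44 ± 0.16), Arrdc2 (1.42 ± 0.11), Plin4 (1.35 ± 0.14), Ddit4 (1.32 ± 0.11), Cdkn1a (1.29 ± 0.11), Tma16 (1.28 ± 0.17) and Sgk3 (1.28 ± 0.10). The receptor co-chaperone gene Fkbp5 rose by 1.18 ± 0.12 (adjusted p = 0.000973) in this set, against -0.05 in replicates 4 and 5. The largest falls were those of Trim59 (-1.33 ± 0.11), Depdc7 (-0.99 ± 0.12), Tek (-0.96 ± 0.13), Kdr (-0.95 ± 0.18), Gm10863 (-0.91 ± 0.13), Gbp11 (-0.83 ± 0.14), Fbxo32 (-0.81 ± 0.11), Pik3c2b (-0.78 ± 0.09), Sall1 (-0.77 ± 0.13) and Tnfaip6 (-0.72 ± 0.10). In replicates 4 and 5 these largest rises kept their direction, at 0.39 for Setdb2, 0.575 for Hif3a, 1.21 for Slc25a13, 0.37 for Zfp36, 0.645 for Arrdc2, 0.33 for Plin4, 0.10 for Ddit4, 2.56 for Cdkn1a, 0.23 for Tma16 and 1.12 for Sgk3. Not all rising genes among the 101 did so. Mxd4 changed by 0.77 in replicates 1 to 3 and -0.57 in replicates 4 and 5, Net1 by 0.72 and -0.51, and Phactr4 by 0.68 and -0.48. These 3 genes are named here after their values were seen. Of the largest falls, 6 had positive changes in replicates 4 and 5, none of them called, with 0.275 for Trim59, 0.12 for Depdc7, 0.37 for Tek, 0.215 for Kdr, 0.075 for Sall1 and 0.41 for Tnfaip6. Trim59 and Tnfaip6 each had a distant value in Cx30GRko Dex replicate 4, an array that stood apart. Over all arrays these 6 genes were not called (adjusted p = 0.499, 0.335, 0.541, 0.537, 0.584 and 0.725). The other falls were -0.24 for Gm10863, -0.68 for Gbp11, -0.47 for Fbxo32 and -0.07 for Pik3c2b.

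Among the receptor targets 16 of 30 rose in replicates 1 to 3, 29 adjusted over the list alone. These included the NF-kB inhibitor gene Nfkbia (0.82, adjusted p = 0.00237) and the transcription factor gene Klf15 (0.84, 0.0275), both chosen after their values were seen. Of the endothelial markers 3 fell in this set, 5 adjusted over the list alone, and the list was shifted down (adjusted p = 8.52e-06; adjusted p = 0.153 with an estimated correlation). The 3 were the vascular receptor genes Tek (adjusted p = 0.00752) and Kdr (0.0427) and the thyroid hormone transporter gene Slco1c1 (-0.58 ± 0.09, 0.017). In replicates 4 and 5 the mean changes of Tek, Kdr and Slco1c1 were 0.37, 0.22 and 0.47. By genotype they were 0.29, -0.26 and -0.25 in control mice and 0.46, 0.69 and 1.195 in Cx30GRko mice, whose Dex arrays of that set stood apart, with an endothelial marker score of 0.601 in replicate 4. Kdr and Slco1c1 were below the saline mean of their array set in 5 of 5 control Dex arrays, and the endothelial median in control mice was -0.16 in replicates 4 and 5.

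The splits argue against chance as the source of the Dex calls, though 100 splits per comparison cannot exclude it. Splits that mix Dex and saline arrays also widen the spread of genes that respond, which lowers their counts. Arrays were exchanged freely between the 2 array sets in these splits. In control mice 1 of the 100 splits of the 10 arrays, the real one, called as many as its 3 genes, and the highest other split called 1. In Cx30GRko mice it was 1 of the 100 splits (4 genes, highest other 1), and for the mean Dex effect 1 of the 100 splits (33 genes, highest other 0). For the median shift of the receptor targets it was 1 of the 100 splits in control mice (0.6201, highest other 0.5242) and 1 of the 100 splits in Cx30GRko mice (0.6529, highest other 0.4866). For the comparisons in which 0 genes were called (limma; at an unadjusted p under 0.05 1165 genes for genotype under saline, 2481 for genotype under Dex and 1253 for the interaction) the splits decide nothing, since each of the 100 splits reaches a count of 0 whatever the data. The highest counts of the other splits were 0, 1 and 2 there, and 4 for the interaction among the Dex genes.

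Replicates 4 and 5 called no Dex gene, and replicates 1 to 3 called 101. Having 2 arrays per group fits in part: 10 of 81 subsets of 2 arrays per group of replicates 1 to 3 also called 0 genes, though the median subset called 9 and the highest 34. A larger spread between arrays of 1 group is consistent with the values too, since the median residual SD in replicates 4 and 5 was 1.763 times that in replicates 1 to 3. A smaller response of the fixed receptor targets could not be told apart from an equal one. Their median was 0.336 against 0.745, a ratio of 0.452 that met the bound set for it. The middle 95% of ratios over sets of resampled members ran from 0.15 to 1.011, a range that treats the members as independent. All 3 stay open, as does a difference between the animals of the sets, which was not tested.

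Over the 101 Dex genes of replicates 1 to 3 the Dex effects in that set tended to be smaller in Cx30GRko than in control mice, though not past the test, with a median signed difference of -0.1436, a ratio of summed effects of 0.792 and 78 of 101 genes smaller (exact two-sided permutation p = 0.14, 400 regroupings; -0.1253 for the 79 rising genes, exact p = 0.265, and -0.1872 for the 22 falling genes, exact p = 0.055). With meningeal and root markers as a covariate the difference was still -0.1043, so the measured marker scores did not account for all of it. These scores differed by group, at 0.397 in control saline, -0.295 in control Dex, -0.187 in Cx30GRko saline and 0.086 in Cx30GRko Dex arrays. With 12 arrays the covariate cannot be cleanly separated from the difference tested, so more such tissue in some arrays stays open as a source. A single array is argued against, since leaving out 1 of the 12 arrays gave -0.1965 to -0.1096. Chance stays open, since 28 of the 200 splits gave a difference at least as large (the highest of the other splits 0.2051). Loss of the receptor in the Cx30-Cre cells, the difference the design names, stays open as well: the same genes gave -0.0163 in replicates 4 and 5 (exact p = 0.889), with 0.017 for the 79 rising genes (exact p = 1) and -0.4026 for the 22 falling genes (exact p = 0.611), so the set decides neither way, although the median over all 101 was negative as the test asked. Over the fixed receptor targets the difference was 0.1645 in all arrays (exact p = 0.19) and -0.0786 in replicates 1 to 3 (exact p = 0.51).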
